A study of Homo sapiens with 4 samples.

How the data were processed

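RNA sequencing was done on 4 libraries of 253G1, an established human induced pluripotent stem cell line, grown in mTeSR1 medium on a gelatin nanofiber substrate. The sample records put 2 libraries in the group Domed and 2 in the group Monolayer. In both groups replicate 1 is passage 19 and replicate 2 is passage 23. The labels do not say whether the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

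The column header inside each of the 4 deposited files names the other kind of cell than the sample record and file name do. The sample records were followed, and groups are therefore called the libraries labelled Domed and the libraries labelled Monolayer. If the headers are right, every direction between the kinds reverses.

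The authors deposited FPKM values (fragments mapped to a transcript, scaled by its length and the total mapped), 1 file per library, each with 23615 rows named by gene symbol. Per the submitters' processing notes, CASAVA 1.8, TopHat and the human build hg19 were used. The tool that made the FPKM values and the gene annotation are not given in the sources used here. The deposited FPKM values were not rescaled. They summed to 445852 and 481312 in the libraries labelled Monolayer (replicates 1 and 2) and to 491177 and 431040 in those labelled Domed. FPKM carries no read totals, so the depth of each library is unknown. The smallest values above 0 shift between libraries by a common factor, from which the relative depth was estimated as 1.10 (Monolayer replicate 2), 1.12 (Domed replicate 1) and 1.49 (Domed replicate 2) times that of Monolayer replicate 1.

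In each file 28 rows carry symbols turned into dates by a spreadsheet. They were not mapped back to genes, and the 2 such symbols that occur more than once were summed. Exact zeros can be failed estimates in FPKM files. POU5F1, which pluripotent cells use, is listed at 0 in all 4 libraries. Genes at 0 are therefore reported as listed at 0, without a fold.

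Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend, two-sided) on log2(FPKM + 1), over the 12135 genes with a mean of at least 1 FPKM. Calls are at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Passage 23 was compared with passage 19 in the same way, ignoring the kind of cell. Gene lists (38, of which 34 had at least 5 measured members) were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The lists, the tests, the alternative settings and the rule for named genes were fixed before the data were examined.

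Named genes are the 10 largest rises and 10 largest falls among called genes with one direction at both passages, the 2 or 3 members with the largest absolute change of each list past its test or of a cell type, and a fixed set of pluripotency, lineage and adhesion genes. Other genes named are said to have been chosen after their values were seen, except those called between the passages without a covariate, which are all given. XIST and Y-linked genes were left out, and the results of a few further items are not reported here.

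The labels give replicate number and passage together, and same-numbered libraries deviated together from their group means (r = 0.26 across genes, which are not independent replicates). The numbers were therefore taken to pair the libraries in the fit with the replicate block. The main fit, fixed before the data were examined, ignores this pairing, so a gene short of its threshold can pass with the block. The fit with the replicate block called 590 genes higher and 380 lower, against 52 and 45 without it, with 1 residual degree of freedom against 2. After moderation, in which limma borrows the spread of other genes, the total was 17.6 with the block and 7.9 without. The smaller p-values with the block therefore lean more on the spread of other genes.

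The tests were run on simulated data with 200 changed genes among 12135 in each of 10 draws of the comparison of Domed with Monolayer. With no passage effect simulated, the fit without block recovered 73.4% of changes of 1 log2 unit and 99.9% of changes of 2, and 9.69% of its calls were false. With a passage effect it recovered 37.9% and 98.7%, with 0.51% false calls. The fit with the replicate block recovered 93.1% and 100% in that case with 12.2% false calls, and 19.9% of its calls were false with no passage effect. In these simulations its calls therefore held more false ones than the nominal 5%. So did those of the fit without block when no passage effect was simulated. The share of false calls in the real counts is unknown. In simulated lists shifted by 0.5 log2 units, camera found 100 of 100 at the preset correlation and 8 of 100 with an estimated correlation. Members of these lists were simulated to vary independently. The counts therefore do not show which setting is right for lists whose members vary together.

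Alternatives covered the pseudocount, filters, scaling, the block, the trend and leaving out each library. Leaving out a library leaves 1 in its group, so the spread then comes from the other group alone and a lost call can reflect the smaller design. Added after seeing the data were fits without small non-coding RNAs and fits with the trend against GC content and transcript length removed from each library (lowess, span 0.3). GC content and length came from the longest GENCODE 29 transcript of each symbol, read with Biostrings 2.70.1, and were found for 97.7% of tested genes. That annotation is on another build than the deposited values, so no coordinates are given. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.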

Results

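Gene expression was measured by RNA sequencing in 4 libraries of the human induced pluripotent stem cell line 253G1, grown on gelatin nanofibers. Cells with the label Domed and cells with the label Monolayer were each sequenced at passage 19 and at passage 23, giving 2 libraries per kind. Values are FPKM, as mean ± SD (n = 2) unless said otherwise. Between 15881 and 16364 genes were above 0 in a library. Directions follow the sample records, and all of them reverse if the headers inside the files, which name the other kind, are right.

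The main comparison asked which genes differed between the libraries labelled Domed and those labelled Monolayer. The libraries labelled Domed held less of the transcripts of NODAL, the growth factor that maintains human pluripotency and patterns the early embryo, at 32.9 ± 2.87 against 108 ± 10.6 FPKM. They also held less of the NODAL antagonists LEFTY2 (47.3 ± 2.59 against 102 ± 2.98) and CER1 (1.61 ± 0.360 against 7.60 ± 3.02). LEFTY1, named after its value was seen, was not called (log2 change 0.087, limma adjusted p = 0.873). The libraries labelled Domed held more FN1, which encodes the matrix protein fibronectin (58.3 ± 5.98 against 20.4 ± 3.14), and more TCF7L1, a repressor of WNT target genes (83.7 ± 5.67 against 30.3 ± 1.69). Over all 12135 genes tested, limma called 52 higher and 45 lower in the libraries labelled Domed, and 1731 genes had an unadjusted p under 0.05. With the replicate block the counts were 590 and 380. The 97 genes called without the block were also called with it, in a fit to the same libraries. For all 97 both libraries of a kind lay apart from both of the other, as for 45.6% of tested genes. That fixes one direction at both passages, which is therefore no separate support for these calls. Leaving out Monolayer replicate 1 left 11 genes higher and 18 lower, leaving out Monolayer replicate 2 left 23 and 27, and leaving out Domed replicate 2 gave 81 and 54.

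Among the 10 largest falls, ABHD12B went from 23.6 ± 3.03 to 1.77 ± 0.261 FPKM (limma log2 change -3.15, SE 0.191, adjusted p = 0.000427). LINC-ROR, a long non-coding RNA of pluripotent cells, went from 26.4 ± 1.61 to 2.48 ± 0.728 (log2 change -2.99). DPPA5, a marker of naive pluripotency, went from 21.0 ± 0.199 to 3.14 ± 0.618 (log2 change -2.41). The others with values above 0 in every library were MAGEH1 (-2.72) and MAGEA4 (-2.19) of the MAGE family, the germ cell RNA-binding gene RBM46 (-2.43), IGFBP7 (-2.39), which encodes a secreted growth factor binding protein, and SORBS3 (-2.16), which encodes the adhesion protein vinexin. MAGEA4 lost its call without Monolayer replicate 1 (limma adjusted p = 0.0517).

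The largest rises among genes above 0 in every library were ADM, a peptide hormone gene induced by hypoxia, at 6.14 ± 1.47 against 0.439 ± 0.0948 FPKM (limma log2 change 2.30, SE 0.236, adjusted p = 0.00837), and CADM4, a cell adhesion molecule, at 10.5 ± 1.83 against 1.34 ± 0.0674 (log2 change 2.30). GRPR, the receptor of gastrin-releasing peptide, stood at 68.4 ± 24.2 against 15.7 ± 4.88, GNG4, a G protein subunit gene, at 15.4 ± 1.76 against 3.501 ± 1.28, and FAAH, which breaks down endocannabinoids, at 14.1 ± 0.703 against 3.17 ± 0.872. GRPR lost its call without Monolayer replicate 2 (limma adjusted p = 0.0882) and GNG4 without Monolayer replicate 1 (0.0802).

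The remaining 7 of these 20 genes are small non-coding RNAs listed at 0 in both libraries of a kind, for which no fold is given. RNU6ATAC, a spliceosomal RNA, was listed at 0 in the libraries labelled Monolayer and at 189.1 and 100.9 FPKM in those labelled Domed. SNORA71D was at 70.7 and 117 in the latter, SNORA11E at 79.2 and 42.5, SNORA7A at 50.9 and 35.2 and SNORA23 at 9.45 and 5.85, each listed at 0 in both of the former. SNORD97 was at 186 and 67.3 and SCARNA10 at 3.73 and 3.26 in the libraries labelled Monolayer and at 0 in those labelled Domed, and SCARNA10 lost its call without Monolayer replicate 1 (limma adjusted p = 0.051). Without all small non-coding RNAs, an analysis chosen after seeing the data, 97 genes were called higher and 74 lower.

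**Figure D1:**
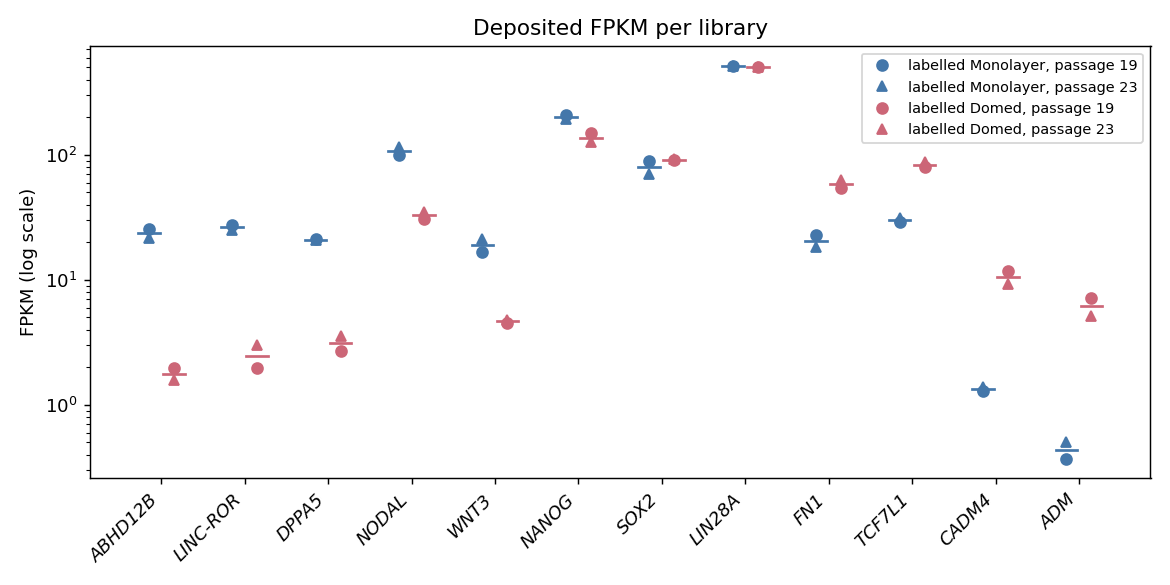
FPKM on a log axis for 12 genes in each of the 4 libraries, with circles for passage 19, triangles for passage 23 and a short line at the mean of each kind. Both libraries of a kind lie apart from both of the other for each of the 12 genes, as they do for 45.6% of all tested genes. The gap is small for SOX2 and for LIN28A, which lies near 500.96 to 514.03 FPKM in all 4.

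The pluripotency lists compared genes linked to different states of pluripotency. Of 24 measured genes linked to primed pluripotency, the state of conventional human stem cells, 23 were higher in the libraries labelled Domed, with a median log2 change of 0.42 (camera adjusted p = 2.33e-06, 0.524 with an estimated correlation). TCF7L1, NLGN4X (19.2 ± 3.26 against 7.24 ± 1.78) and SOX3 (6.37 ± 0.513 against 2.35 ± 0.174) rose, and DUSP6, an antagonist of ERK signalling, was at 5.10 ± 2.58 against 1.15 ± 0.0327 (limma adjusted p = 0.0828, 0.000595 with the replicate block). Of 18 naive pluripotency genes 14 were lower, with a median of -0.41 (camera adjusted p = 0.000128, 0.524 with an estimated correlation). DPPA5 fell, KLF5 was at 0.921 ± 0.271 against 3.60 ± 0.191 (limma adjusted p = 0.0534, 0.00134 with the block), and VENTX at 13.1 ± 3.91 against 32.2 ± 1.67 (0.0516, 0.000167 with the block). Calls of single genes numbered 3 higher among the primed genes and 1 lower among the naive genes, and adjusted over the list alone 9 higher and 1 lower among the former, and 2 higher and 8 lower among the latter. With the replicate block they were 9 higher and 1 lower, and 2 higher and 8 lower. TCF7L1, NLGN4X and SOX3 each lost theirs without either Monolayer library (limma adjusted p from 0.0569 to 0.299), at log2 changes from 1.08 to 1.52, and NLGN4X and SOX3 also without Domed replicate 1 (0.0716 and 0.0572) and with median-ratio scaling (0.0602 and 0.0682). SOX3 also lost its call without Domed replicate 2 and with quantile normalization (limma adjusted p = 0.0842 and 0.0667).

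The core pluripotency list did not pass (23 measured genes, median -0.10, camera adjusted p = 0.503), with 1 gene called lower. That gene was ZFP42, also called REX1 (log2 change -1.71), named after its value was seen. SOX2 stood at 91.4 ± 1.43 FPKM in the libraries labelled Domed and 79.9 ± 13.2 in those labelled Monolayer, LIN28A at 503 ± 3.30 and 512 ± 3.10, and NANOG at 137 ± 15.8 and 201 ± 7.94, none past the threshold (limma adjusted p = 0.682, 0.968 and 0.239). DNMT3B, a DNA methyltransferase, was at 557 ± 93.9 and 718 ± 50.4, OTX2 at 5.05 ± 1.93 and 4.61 ± 1.36, ZIC2 at 12.4 ± 6.99 and 9.85 ± 2.90, and TFCP2L1 at 1.90 ± 0.515 and 2.51 ± 0.296, also short of it. KLF4 was at 1.44 ± 0.958 against 3.25 ± 0.181 (limma adjusted p = 0.245, 0.0251 with the block) and DPPA3 at 2.81 ± 0.109 against 1.30 ± 0.658 (0.246, 0.0464 with the block). POU5F1 was listed at 0 in all 4 libraries.

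Lists of NODAL/TGF-beta signalling, WNT targets, primitive streak and germ cells were lower in the libraries labelled Domed by camera at the preset correlation, and none passed with an estimated correlation (adjusted p = 0.524 for each). Of 21 measured NODAL/TGF-beta pathway genes 17 were lower (median -0.27, camera adjusted p = 0.000138), and NODAL, CER1 and LEFTY2 fell. Of 10 WNT targets 7 were lower (median -0.45, 0.00509) and 3 higher. WNT3, itself a WNT gene and also in the primitive streak list, fell, at 4.65 ± 0.210 against 18.98 ± 3.03 FPKM. SP5 (log2 change -1.47, limma adjusted p = 0.0534, 0.00121 with the block) and TCF7 (-0.68, 0.174, 0.0252 with the block) did not pass without the block. The 3 higher ones were NKD1 (0.36), FZD8 (0.15) and BAMBI (0.65, limma adjusted p = 0.175, 0.0187 with the block), and ZNRF3 was near 0 (-0.039). These 4 were named after their values were seen. Of 6 measured primitive streak and mesoderm genes, from a list of 21, 5 were lower (median -0.71, camera adjusted p = 0.00507). WNT3 was called, and FGF8 (log2 change -1.54, limma adjusted p = 0.0632, 0.000232 with the block) and MIXL1 (-1.36, 0.0685, 0.00109 with the block) were short of the threshold. The rest, named after their values were seen, were KDR (-0.055), TBX6 (-0.048) and SNAI1 (0.393). The median falls between these and the genes that were clearly lower, and no measured member lay near it. Of 10 germ cell genes 9 were lower (median -0.46, camera adjusted p = 0.000373), with DND1 called, at 3.99 ± 0.176 against 16.2 ± 0.00233, and MAEL (log2 change -1.44, limma adjusted p = 0.056, 0.00169 with the block) not. Calls adjusted over the list alone were 1 higher and 6 lower for NODAL/TGF-beta, 1 and 5 for WNT targets, 0 and 3 for primitive streak, and 1 and 5 for germ cells. The WNT list lost its call without Monolayer replicate 1 (camera adjusted p = 0.0638). So did CER1, LEFTY2 and DND1 (limma adjusted p = 0.214, 0.202 and 0.0515), while WNT3 lost its call without Monolayer replicate 2 (0.0574). CER1 lost its call also without Domed replicate 2 (limma adjusted p = 0.0692), LEFTY2 without Monolayer replicate 2 and without Domed replicate 1 (0.148 and 0.0625), and both with median-ratio scaling (0.0582 and 0.0507).

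**Figure D2:**
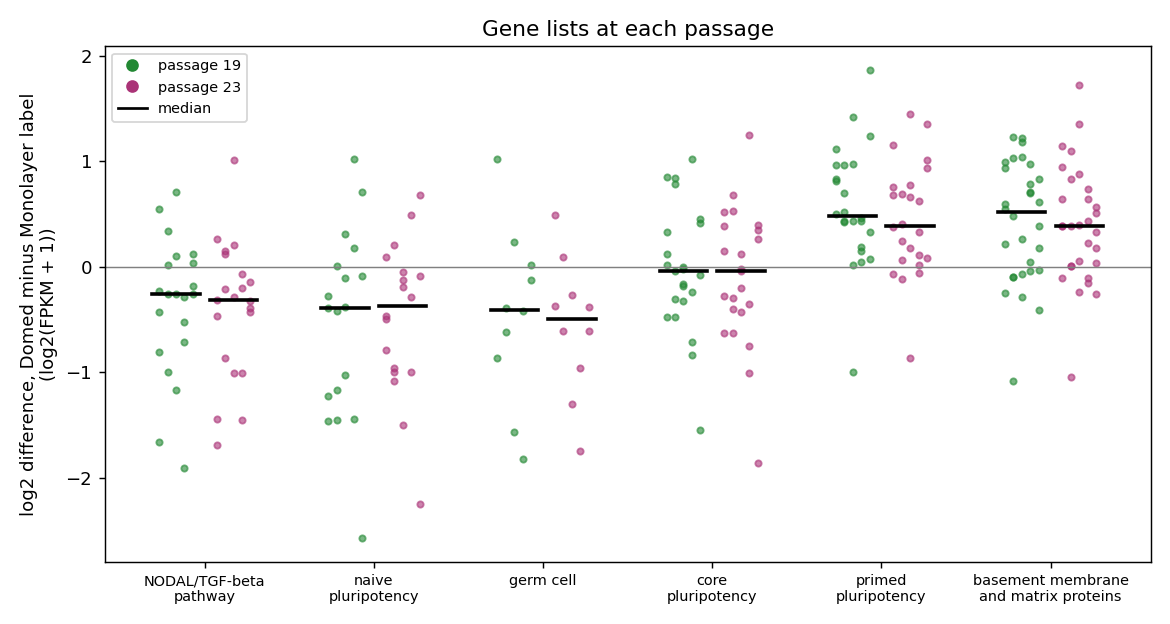
Log2 differences of log2(FPKM + 1), the libraries labelled Domed minus those labelled Monolayer, for each measured gene of 6 lists at passage 19 and at passage 23, with black lines at the medians. The primed pluripotency genes lie mostly above 0, with medians of 0.48 at passage 19 and 0.39 at passage 23, while the core pluripotency genes scatter around 0 with medians of -0.04 and -0.04.

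Basement membrane and matrix genes stood higher in the libraries labelled Domed for 21 of 30 members (median 0.47, camera adjusted p = 0.000128, 0.709 with an estimated correlation). FN1 and COL6A1, the latter named after its value was seen, rose, and COL2A1 (2.28 ± 0.621 against 0.413 ± 0.0503 FPKM) and COL5A2 (5.58 ± 1.28 against 1.92 ± 0.380) were short of the threshold without the block (limma adjusted p = 0.0832 and 0.0708) and past it with the block (0.00475 and 0.000877). With the block 12 matrix genes were higher and 1 lower, and adjusted over the list alone 10 and 1. With the GC and length trend removed the median of the matrix list was 0.29 (camera adjusted p = 0.00968), and FN1 lost its call without either Monolayer library (limma adjusted p = 0.051 and 0.0941). Hypoxia genes were higher for 17 of 21 members (median 0.36, camera adjusted p = 0.0038, 0.791 with an estimated correlation), with ADM called. The list also differed between the passages (median -0.54 at passage 23, camera adjusted p = 1.85e-11, 0.925 with an estimated correlation). EGLN3 was at 11.5 ± 1.51 against 4.90 ± 0.328 (limma adjusted p = 0.0501, 0.000561 with the block) and MXI1 at 3.75 ± 1.84 against 1.51 ± 0.587 (0.260, 0.0131 with the block). Glycolysis genes were higher for 20 of 22 (median 0.28, camera adjusted p = 0.00509, 0.791 with an estimated correlation), with no single call. SLC2A1 was at 117 ± 56.1 against 73.4 ± 20.03, HK2 at 19.4 ± 3.52 against 12.4 ± 2.33 (limma adjusted p = 0.245, 0.0276 with the block). PDK1 went the other way, at 8.43 ± 4.87 against 13.5 ± 5.76 (0.501, 0.0195 with the block). Both lists lost their call without Monolayer replicate 2 (camera adjusted p = 0.322 and 0.224) and without Domed replicate 1 (0.628, with the median at -0.015, and 0.442).

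Few markers of differentiated cell types were called. Neuroectoderm genes were higher for 6 of 7 members in the libraries labelled Domed (median 0.45, camera adjusted p = 0.00509, 0.524 with an estimated correlation, 0.13 without Domed replicate 2). SOX3 rose, STMN2 was at 3.61 and 1.58 FPKM against 0.114 and 0 (limma adjusted p = 0.0627, 0.000538 with the block), and NCAM1 at 1.85 ± 0.00409 against 0.966 ± 0.179 (0.345). The lists for neural crest (7 genes, median 0.20), trophoblast and amnion (8 genes, -0.04) and fibroblast (11 genes, 0.08) did not pass (camera adjusted p = 0.123, 0.958 and 0.941). FOXD3, a neural crest and stem cell factor, was at 7.91 ± 1.29 against 3.10 ± 1.04 (limma adjusted p = 0.0828, 0.000595 with the block), B3GAT1 at 9.16 ± 0.913 against 6.69 ± 0.629. IGFBP3 was at 1.90 ± 0.727 against 0.640 ± 0.0429 and KRT7 at 4.17 ± 0.182 against 2.41 ± 0.563. In the fibroblast list IGFBP7 fell and S100A4 was at 21.2 ± 2.75 against 45.5 ± 8.14 (limma adjusted p = 0.0599, 0.00127 with the block). Of that list 4 genes were higher and 2 lower with the block. Too few members were measured to test endoderm (3, CER1 called), surface epithelium (4, SFN called lower and named after its value was seen) and endothelium and blood (4, none called by limma, each with an unadjusted p above 0.05).

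Single lineage genes were near the floor. T, the mesoderm gene brachyury, was at 0.911 and 0.460 FPKM in the libraries labelled Monolayer and 0 and 0.133 in those labelled Domed, and PAX6, SOX17 and GATA3 were below 0.3 in every library. Of the adhesion genes, CDH1 stood at 54.4 ± 1.05 and 56.0 ± 3.40, CDH2 at 10.7 ± 0.521 and 9.87 ± 0.426, ITGB1 at 182 ± 63.1 and 179 ± 15.5, and ITGA6 at 29.4 ± 0.982 and 31.7 ± 2.12 in the libraries labelled Domed and Monolayer. VIM was at 38.2 ± 12.2 and 32.4 ± 2.03 and COL1A1 at 65.5 ± 27.7 and 59.0 ± 3.39. None of these 6 passed the threshold of limma (adjusted p from 0.748 to 0.979).

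Lists of growth and cell cycle had small medians. The 4 given here passed camera at the preset correlation and none passed with an estimated correlation (adjusted p = 0.791 for each). Ribosomal protein genes had a median of -0.14 over 75 members (camera adjusted p = 0.00509, 0.0571 with the replicate block) and no single call. RPL39 was at 2458 ± 783 against 3382 ± 20.4 FPKM, RPS3A at 1365 ± 567 against 1794 ± 31.4 and RPL9 at 1115 ± 428 against 1429 ± 26.3. Nuclear genes of oxidative phosphorylation had a median of -0.07 over 61 members (camera adjusted p = 0.0192), led by NDUFB9 (171 ± 4.82 against 302 ± 33.0, limma adjusted p = 0.105, 0.0312 with the block), NDUFA8 (70.6 ± 5.18 against 109 ± 19.04) and NDUFC1 (31.9 ± 3.19 against 45.1 ± 5.32). G2 and M phase genes had a median of -0.20 over 32 members (0.00507). ANLN was at 14.03 ± 1.34 against 22.3 ± 2.67 (limma adjusted p = 0.173, 0.0281 with the block), CENPE at 6.70 ± 1.98 against 10.3 ± 0.697 (0.290, 0.0487 with the block) and CDK1 at 25.8 ± 10.4 against 36.9 ± 1.30. Histone genes had a median of -0.18 over 28 members (camera adjusted p = 0.0241). HIST1H1A was at 2.99 ± 2.72 against 14.7 ± 6.52 (limma adjusted p = 0.0986, 1.52e-06 with the block), HIST1H1C at 29.8 ± 7.35 against 63.5 ± 24.7 (0.161, 0.0011 with the block) and HIST1H2AE at 28.7 ± 21.3 against 41.1 ± 9.93. The oxidative phosphorylation and histone lists lost their call with the GC and length trend removed, an analysis added after seeing the data (camera adjusted p = 0.103 and 0.163), with medians of -0.06 and -0.13. All 4 lost theirs without Monolayer replicate 2 (camera adjusted p = 0.0515 for the ribosomal, 0.645 for the oxidative phosphorylation, 0.208 for the G2 and M and 0.747 for the histone list). Without Domed replicate 2 the first 3 of these lost theirs (0.943, 0.234 and 0.056), with medians above 0 for the ribosomal and oxidative phosphorylation lists (0.073 and 0.065). The histone list lost its call without Domed replicate 1 (camera adjusted p = 0.0852, median 0.15). So did the ribosomal and histone lists with quantile normalization (0.0865 and 0.0591), and the histone list with median-ratio scaling (0.0554).

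The lists in this paragraph did not pass in the main fit. Of YAP/TAZ targets, genes switched on by mechanical and growth signals, 14 of 20 were higher (median 0.26, camera adjusted p = 0.0674, 0.0423 with median-ratio scaling) and CTGF (log2 change 1.39) and CYR61 (1.15) rose, named after their values were seen. Medians and camera adjusted p were 0.25 and 0.0871 for focal adhesion, 0.17 and 0.115 for actomyosin, 0.20 and 0.113 for mesenchymal transition, 0.20 and 0.366 for integrins, 0.11 and 0.416 for cell-cell adhesion and 0.09 and 0.794 for matrix remodelling. They were -0.14 and 0.144 for FGF/ERK targets, 0.20 and 0.911 for BMP targets, 0.04 and 0.416 for cholesterol synthesis, and 0.11 and 0.399 for the integrated stress and unfolded protein response. They were -0.05 and 0.199 for heat shock, 0.03 and 0.972 for immediate early genes, -0.06 and 0.113 for S phase and -0.05 and 0.859 for DNA methylation enzymes. With the GC and length trend removed, medians moved to 0.15 for YAP/TAZ targets (camera adjusted p = 0.156), 0.12 for focal adhesion (0.322), 0.08 for actomyosin (0.156), 0.10 for integrins (0.484) and 0.02 for cell-cell adhesion (0.665). They moved to 0.05 for BMP targets (camera adjusted p = 0.665), 0.09 for cholesterol synthesis (0.384) and -0.03 for DNA methylation enzymes (0.541). The 13 genes of the mitochondrial genome were not analysed here. In all, camera put 15 of 34 lists past the threshold at the preset correlation, 10 of them lower, and 0 with an estimated correlation (1 list at an unadjusted p under 0.05) or with fry (8 lists). Some of these lists share members, so they are not separate results. SOX3 is in both the primed and neuroectoderm lists, WNT3 in both the WNT and primitive streak lists, and DPPA3 in both the naive and germ cell lists. HK2, SLC2A1 and PDK1 are in both the glycolysis and hypoxia lists.

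Across all tested genes, the difference between the kinds rose with the GC content of the transcript (Spearman rho = 0.381 across genes, which are not independent replicates). The median log2 change was -0.14 in the fifth of genes with the lowest GC content and 0.20 in the fifth with the highest. Libraries of a kind also differed, as the deviation from the mean of all 4 had a rho with GC content of -0.352 and -0.188 in those labelled Monolayer and 0.116 and 0.375 in those labelled Domed. The difference between the passages had a rho of 0.199. With the trend against GC content and length removed, a step chosen after seeing the data, 32 genes were called higher and 39 lower, of which 66 were among the 97. With the replicate block as well the counts were 321 and 298.

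The passages were compared to set the difference between the kinds beside the other labelled difference. SNORA21 and SNORA80, small nucleolar RNAs, were listed at 0 in both passage 19 libraries and at 122.0 and 54.0 FPKM, and 98.6 and 44.3 FPKM, at passage 23. RPL21, a ribosomal protein gene with many near-identical pseudogenes, was at 60.2 and 54.4 at passage 19 and 0.046 and 0.035 at passage 23, so its value is uncertain. These 3 genes, 2 higher and 1 lower, were all that limma called, and 592 had an unadjusted p under 0.05 where chance gives 607. With the kind of cell as a covariate, the replicate block model, 70 were higher and 161 lower, among the latter BNIP3 (77.9 and 76.7 FPKM against 25.3 and 18.2) and P4HA1 (19.5 and 28.8 against 8.73 and 8.998), both hypoxia-induced and named after their values were seen. Of the gene lists, 10 passed camera at the preset correlation and none with an estimated one (adjusted p = 0.925 for each). Medians at passage 23 against passage 19 were 0.58 for histones (camera adjusted p = 2.69e-17), -0.54 for hypoxia, 0.23 for S phase (1.78e-06), 0.24 for cholesterol synthesis (0.000491) and -0.17 for glycolysis (0.000337). They were 0.18 for focal adhesion (camera adjusted p = 0.000675), -0.18 for ribosomal proteins (0.00126), 0.15 for heat shock (0.00317), 0.11 for actomyosin (0.00479) and 0.19 for DNA methylation enzymes (0.0463). Without one library at a time the counts of genes ran from 4 to 8 higher and from 1 to 6 lower.

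The difference between the kinds was also taken at each passage. Across 12135 genes the log2 differences at passage 19 and passage 23 correlated with Pearson's r = 0.431 and Spearman's rho = 0.506, across genes, which are not independent replicates. The direction was the same for 64.8% of genes. The libraries of a kind lay wholly above or below the other for 45.6% of genes, where chance gives 33.3% if all libraries are interchangeable. A shared passage effect would change that share. So could a GC trend that follows the kinds, which could also raise the correlation and the share with one direction. The difference between the kinds had a rho with GC content of 0.296 at passage 19 and 0.359 at passage 23. The agreement between passages was not computed with that trend removed.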

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

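Results are given here where the libraries labelled Domed lay above those labelled Monolayer at one passage and below at the other. With 1 library of each kind per passage, none of these differences was tested. The test of the sample links was chosen after the result was seen.

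Among named genes, the log2 difference went from 0.46 at passage 19 to -0.06 at passage 23 for VIM, from 0.50 to -0.07 for ZIC2, from 0.25 to -0.29 for ITGB1, from -0.29 to 0.46 for COL1A1, from -0.082 to 0.001 for CDH1 and from 0.008 to -0.83 for RPL9. Among lists, the median went from 0.11 to -0.41 for ribosomal proteins, from 0.13 to -0.30 for oxidative phosphorylation, from 0.034 to -0.40 for G2 and M phase, from 0.086 to -0.26 for heat shock and from 0 to -0.16 for S phase. It went from -0.067 to 0.38 for fibroblast genes, from 0.22 to -0.09 for BMP targets, from 0.21 to -0.01 for matrix remodelling and from -0.066 to 0.17 for cholesterol synthesis. It went from -0.081 to 0.028 for trophoblast and amnion, from -0.021 to 0.089 for immediate early genes and from 0.045 to -0.003 for DNA methylation enzymes.

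The direction of every difference between the kinds rests on which file belongs to which sample. In 4 of the 4 files the column header names the other kind than the sample record, while the file names follow the record. Nothing in the values marks the shape of the colonies independently of the labels, so a crossed link and a mistake made only in the headers cannot be told apart. Sizes, adjusted p and membership of the called genes do not depend on it.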

How the results depend on the processing

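Fits without small non-coding RNAs and with the GC and length trend removed were chosen after seeing the data. Genes higher in the libraries labelled Domed numbered 52, and 4 with no filter, 34 rescaled to one FPKM sum, 24 with median-ratio scaling, 108 among genes above 0 in all 4 libraries, 590 with the replicate block, 97 without small non-coding RNAs, 32 with the trend removed, 321 with trend removed and block, and 11 to 81 without 1 library. Genes lower numbered 45, and 0 with no filter (limma, 2161 genes at an unadjusted p under 0.05), 81 among genes above 0 in all 4, 380 with the block, 74 without small non-coding RNAs, 298 with trend removed and block, and 18 to 60 without 1 library. Of the 97 calls, 78, 67, 36 and 25 were lost without Monolayer replicate 1, Monolayer replicate 2, Domed replicate 1 and Domed replicate 2, and 0 changed sign. Lists past the threshold numbered 15, 0 with an estimated correlation or fry, and 11 to 16 without 1 library. At passage 23, 2 genes were higher, 70 with the kind as covariate (replicate block model) and 4 to 8 without 1 library, and 1 was lower, 161 and 1 to 6. The correlation between passages ran from 0.384 to 0.437 over the settings in which it was computed, which do not include those with the trend removed. The cause of these changes was not tested.

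Without 1 library the log2 change of named genes that were not called took both signs, from -0.10 to 0.021 for CDH1, -0.12 to 0.52 for VIM, -0.34 to 0.78 for ZIC2, -0.24 to 0.43 for OTX2, -0.38 to 0.34 for ITGB1, -0.35 to 0.52 for COL1A1 and -1.50 to 0.11 for HIST1H2AE. List medians did so from -0.19 to 0.19 for BMP targets, -0.037 to 0.0070 for trophoblast and amnion, -0.056 to 0.16 for fibroblast, -0.070 to 0.21 for matrix remodelling, -0.015 to 0.69 for hypoxia, -0.19 to 0.065 for oxidative phosphorylation, -0.38 to 0.073 for ribosomal proteins, -0.47 to 0.15 for histones, -0.22 to 0.25 for cholesterol synthesis, -0.23 to 0.13 for heat shock, -0.0064 to 0.094 for immediate early genes, -0.27 to 0.076 for S phase and -0.12 to 0.022 for DNA methylation enzymes. With the trend removed, with or without the replicate block, medians turned to -0.15 for fibroblast, -0.020 for matrix remodelling, 0.0059 for heat shock and -0.14 for immediate early genes, the last also to -0.0015 with median-ratio scaling and -0.013 with quantile normalization. Beyond the values given in this text, the block changed no other call of a gene or list reported in it. Of single genes short of the threshold, DUSP6, FGF8, STMN2, EGLN3, HIST1H1A and HIST1H2AE came past it without Domed replicate 2, VENTX without Domed replicate 1, VENTX, EGLN3 and S100A4 with quantile normalization, and VENTX and EGLN3 with pseudocount 0.1. CER1, LEFTY2, NLGN4X and SOX3 lost their call also when rescaled to one FPKM sum (limma adjusted p from 0.0537 to 0.0645). Without 1 library, lists that did not pass came past the threshold of camera in some fits: S phase without Monolayer replicate 1 (adjusted p = 0.00108) and Domed replicate 2 (0.00386), heat shock without Monolayer replicate 1 (0.00821), focal adhesion and actomyosin without Domed replicate 1 (0.00335 and 0.0221) and without Monolayer replicate 2 (0.0467 and 0.0389), and cholesterol synthesis, lower, without Domed replicate 2 (0.000898). The depth of each library is unknown, which limits what can be said of low genes.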

Other observations

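All genes and lists in this part, and the test of REST, were chosen after the results were seen, while the bounds of the test of a GC trend for the REST targets were set before its result was known. That a bound must be passed by more than the bootstrap SD was decided after the values of both tests were seen, and the bounds for less REST were rewritten after its first test. Of the MAGE family, some of whose members are active in germ cells and tumours, 11 were measured and 3 were called lower in the libraries labelled Domed: MAGEH1, MAGEA4 and MAGEA8 (0.331 against 4.89 FPKM). With the replicate block 4 were called lower, MAGEB2 being added (limma adjusted p = 0.0522, 0.000463 with the block), and 1 higher, MAGED4B (0.213, 0.0254 with the block). The median of the family was 0.02, with 6 higher and 5 lower, and it pools unlike subfamilies. MAGEA4, MAGEA8 and MAGEB2 were at log2 changes of -2.19, -2.12 and -1.54. MAGED1 (52.9 against 38.2) and MAGED2 (118 against 114) were not called by limma (adjusted p = 0.353 and 0.972). Of 4 measured transcripts linked to LTR7, a retroviral promoter active in pluripotent cells, ABHD12B and LINC-ROR fell, while ESRG was at 292 against 331 FPKM and SCGB3A2 at 13.5 against 12.6 (limma adjusted p = 0.758 and 0.874). Of 14 measured imprinted genes 12 were higher, with a median log2 change of 0.38 and 0 calls by limma (2 with the replicate block). SNURF was at 496 against 216 FPKM (limma adjusted p = 0.0825, 0.00385 with the block) and SNRPN at 549 against 387 (0.303, 0.271 with the block). MYC stood at 37.8 ± 0.321 against 19.9 ± 1.25 FPKM (limma adjusted p = 0.0592, 0.00243 with the replicate block).

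Switches of small non-coding RNAs between 0 and at least 10 FPKM were counted within and between the kinds, without a test. There were 21 between the 2 libraries labelled Monolayer and 14 between those labelled Domed, against 26 between the kinds at passage 19 and 15 at passage 23, and 38 of the 41 genes at 0 in a library and at least 10 in another were small RNAs. Of small RNAs 5 were at 0 in both libraries of a kind and at least 10 in both of the other.

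REST, a repressor of neuronal genes, was at 12.5 ± 1.20 FPKM in the libraries labelled Domed and 27.5 ± 4.01 in those labelled Monolayer (limma adjusted p = 0.0501, 0.000684 with the replicate block). Of 28 measured REST targets 25 were higher where REST was lower, with a median log2 change of 0.46, and KIF1A was the gene called (36.8 against 12.5 FPKM). With the replicate block 9 targets were called higher and 0 lower. Of 10000 random lists matched on expression and GC content 0% reached that median, the highest of them being at 0.42. This does not decide whether less REST is the cause, since the list was chosen after values were seen and random lists ignore correlation between its members. The targets are rich in GC (median 57.9% against 48.8% for all tested genes). Removing the GC and length trend lowered their median to 0.31 (bootstrap SD 0.0613). That is above the bound of 0.3 set for each explanation, but by less than the bootstrap SD. Without the rule on spread, added after the values were seen, the bound would have counted against the trend as the whole cause. The margin was small (0.3128 against 0.3), so nothing is concluded from it. The trend goes with part of the difference, and neither explanation was excluded or established.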
